A study of Arabidopsis thaliana with 12 samples.

How the data were processed

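Gene-level counts deposited by the authors were used for 12 libraries in 4 groups of 3, with 33602 genes per library. The submitters' processing notes name StringTie 1.3.3, DESeq2 1.18.1 and the TAIR10 genome; the aligner, the strand and the handling of reads shared between genes are not given in the sources used here. The deposited normalized counts, which the authors call signal, were proportional to the deposited counts within each library. The size factor was taken as the median ratio of count to normalized count, and deviations were at most 5.1e-15 of the count. The counts were taken as raw, which this proportionality cannot show. The authors' deposited tables give log2 fold changes of mock over inhibitor and a p-value, and the sign was turned where they are compared. Gene names came from the reference table, which holds 32835 of the 33602 IDs and gives 10847 of these a symbol other than the ID. Of the genes, 9830 had 0 counts in all libraries.

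Counts were tested with edgeR 4.0.16 in R 4.3.3 on all 12 libraries, with a group for each treatment, TMM scaling, the default low-count filter and robust quasi-likelihood fits, and 17933 genes passed the filter. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a gene called at an adjusted p below 0.05. Each inhibitor was compared with mock and with each other inhibitor. A gene shared by the 3 inhibitors was called in the same direction with each. Log2 fold changes come from the fit. Each standard error (SE) is implied by the test, as the absolute log2 fold change divided by the square root of its F statistic. Levels are CPM (counts scaled to the library total after its TMM adjustment) with the mean and standard deviation of 3 libraries. Where a group had no count, the fold is a lower bound that takes 3 counts in each library of that group.

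Named genes followed a rule fixed before the data were examined. They had to be called, to have a mean of at least 1 CPM over the libraries and to have group values that do not overlap, which happens by chance for 10% of genes with 3 against 3 libraries. The 12 shared genes per direction with the largest smallest change, the 5 largest per direction in each comparison and up to 4 per list were eligible, with all cytokinin oxidases, type-A response regulators and TOR partners. Not all eligible genes are named, and genes without a symbol were limited.

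The 24 gene lists were written from general knowledge of the genes before the values were seen, with 675 members, 1 of which was dropped: cytosolic ribosomal proteins, ribosome biogenesis, cytokinin metabolism, cytokinin response, DNA replication, mitosis and cytokinesis, autophagy, low-energy response, photosynthesis, chlorophyll synthesis, cell wall expansion, auxin response, abscisic acid and dehydration response, glucosinolate synthesis, nitrate assimilation, shoot meristem and leaf growth, circadian clock, TOR pathway components, heat and protein-folding stress, xenobiotic response, jasmonate and wounding, flavonoid and anthocyanin synthesis, root markers and seed storage markers. Each was tested with camera of limma 3.58.1 on voom values with the preset correlation of 0.01, adjusted over 72 tests against mock and over another 72 between inhibitors. The same tests were run with a correlation estimated from the residuals and with fry. Mean levels of a list are the mean over its members of log2 CPM (prior count 2) in each library minus the mock mean, compared with limma with 95% intervals.

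Agreement of the inhibitors was measured across genes with Pearson's correlation and with the covariance of log2 fold changes. Because the 3 inhibitors share their mock libraries, 20 data sets with no change were simulated, mock libraries included, with genes drawn independently around the mock mean. They give the values that sharing simulated controls produces, without deviations that genes of the real mock libraries have in common. DESeq2 1.42.0, limma voom and other scalings, filters and models were alternatives. A simulated comparison with known changes was put through each tool. edgeR recovered 17.9%, 76.1% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 7 unchanged genes called, DESeq2 recovered 29.9%, 77.6% and 95.5% with 17 and limma voom 16.4%, 73.1% and 87.9% with 3. camera called 1 of 1 changed and 0 of 20 unchanged lists. The simulated genes varied independently, so this cannot show how often correlation within a list leads to a false call. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.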

Results

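The series measured the polyadenylated transcriptome of shoots of 4-day-old Arabidopsis Col-0 seedlings, kept for 8 h on plates with an inhibitor of the TOR kinase or with its solvent, DMSO (mock). TOR is the protein kinase that couples nutrient and energy supply to growth. Plates held AZD8055 at 2 µM, KU63794 at 20 µM or TORIN1 at 10 µM, so the doses differed between compounds while the exposure time was the same. Each of the 4 groups had 3 libraries. Total counts of replicates 1 to 3 were 14220537, 10552958 and 7706957 in mock, 11975325, 9557783 and 12272364 with AZD8055, 11947367, 12220409 and 11623964 with KU63794 and 10017439, 9312409 and 14696645 with TORIN1. At these depths a count of 0 allows a level of up to 0.204 to 0.389 CPM, for counting error only. This limit is scaled to the unadjusted library total, while gene levels in CPM are scaled to the library total after its TMM adjustment. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples. Counts were compared for 17933 genes.

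The question in the series title is which genes respond early to loss of TOR activity, whichever inhibitor is used. The gene with the steepest shared rise against a measured mock level was GPT2 (AT1G61800), the glucose-6-phosphate/phosphate translocator of plastids, which went from 1 ± 1.11 CPM in mock to 48 ± 7.7 with AZD8055, 25.6 ± 10.6 with KU63794 and 31.4 ± 2.45 with TORIN1 (mean ± SD, n = 3 each). Its log2 fold changes were 5.48, 4.58 and 4.87 (SE 0.55 each; edgeR adjusted p = 6.14e-05, 0.000262 and 0.00041). NRT2.1 (AT1G08090), a high-affinity nitrate transporter, rose by 4.85, 3.77 and 4.84 log2 units (SE 0.59, 0.64 and 0.59) from a mock level of 0.0685 CPM, below the limit of a count of 0. XTH23 (AT4G25810), a xyloglucan-modifying wall enzyme, rose from 7.78 ± 0.757 CPM to 83.5 ± 25.6, 96.9 ± 44 and 62.7 ± 18.8. SWEET10 (AT5G50790), of the SWEET sugar transporter family, had no count in any mock library and was at least 7.78-fold, 4.24-fold and 3.9-fold higher with AZD8055, KU63794 and TORIN1, taking 3 counts per library as the floor. CYP722A1 (AT1G19630), a cytochrome P450, rose by 3.89, 3.67 and 3.61 (SE 0.61, 0.61 and 0.62), and the MYB regulator of anthocyanin genes PAP2 (AT1G66390) by 3.14, 2.82 and 3.2. Among genes without a symbol, AT2G20142, a TIR-domain gene, rose by 4.37, 4.42 and 4.12 and AT1G20515 by 4.03, 4.69 and 3.74. Mock levels of AT2G20142 (0.114 ± 0.198 CPM), AT1G20515 (0.217 ± 0.376) and PAP2 (0.356 ± 0.309) are not above the 0.389 CPM that a count of 0 allows, so the sizes of these folds are uncertain.

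The deepest shared fall was in AT2G04050, a MATE-family efflux gene, from 19.8 ± 4.59 CPM in mock to 0.74 ± 0.395 with AZD8055, 0.687 ± 0.239 with KU63794 and 1.07 ± 0.284 with TORIN1. Its log2 fold changes were -4.75, -4.82 and -4.18 (SE 0.31, 0.31 and 0.3; edgeR adjusted p = 4.57e-07, 4.17e-07 and 2.28e-06). DTX1 (AT2G04040), another MATE gene, had log2 fold changes of -2.5, -1.95 and -2.61. The reads of such related genes can be shared, so their separate values are uncertain. The beta-galactosidase gene BGAL4 (AT5G56870), known as a gene of low-energy states, fell from 268 ± 64.4 CPM to 39.1 ± 10.1, 64.4 ± 24.1 and 38.7 ± 13.8. GLL22 (AT1G54000), a GDSL-type lipase gene, changed by -2.25, -2.17 and -2.11 (SE 0.36, 0.35 and 0.36). AT1G70880 changed by -3.27, -3.32 and -3.34, to levels of 0.374, 0.37 and 0.356 CPM. These levels are close to what a count of 0 allows, so the sizes of these folds are uncertain. The limit of 0.389 CPM is that of mock replicate 3, and the inhibitor libraries, with larger totals, have lower limits. Of the genes called with all 3 inhibitors, 1111 were higher and 1314 lower, with median log2 fold changes of 0.71 and -0.95 with AZD8055, 0.62 and -0.88 with KU63794 and 0.64 and -0.64 with TORIN1. At least 2-fold changes with all 3 were fewer, 164 higher and 124 lower. Without mock replicate 2 the shared counts were 709 and 801.

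**Figure D1:**
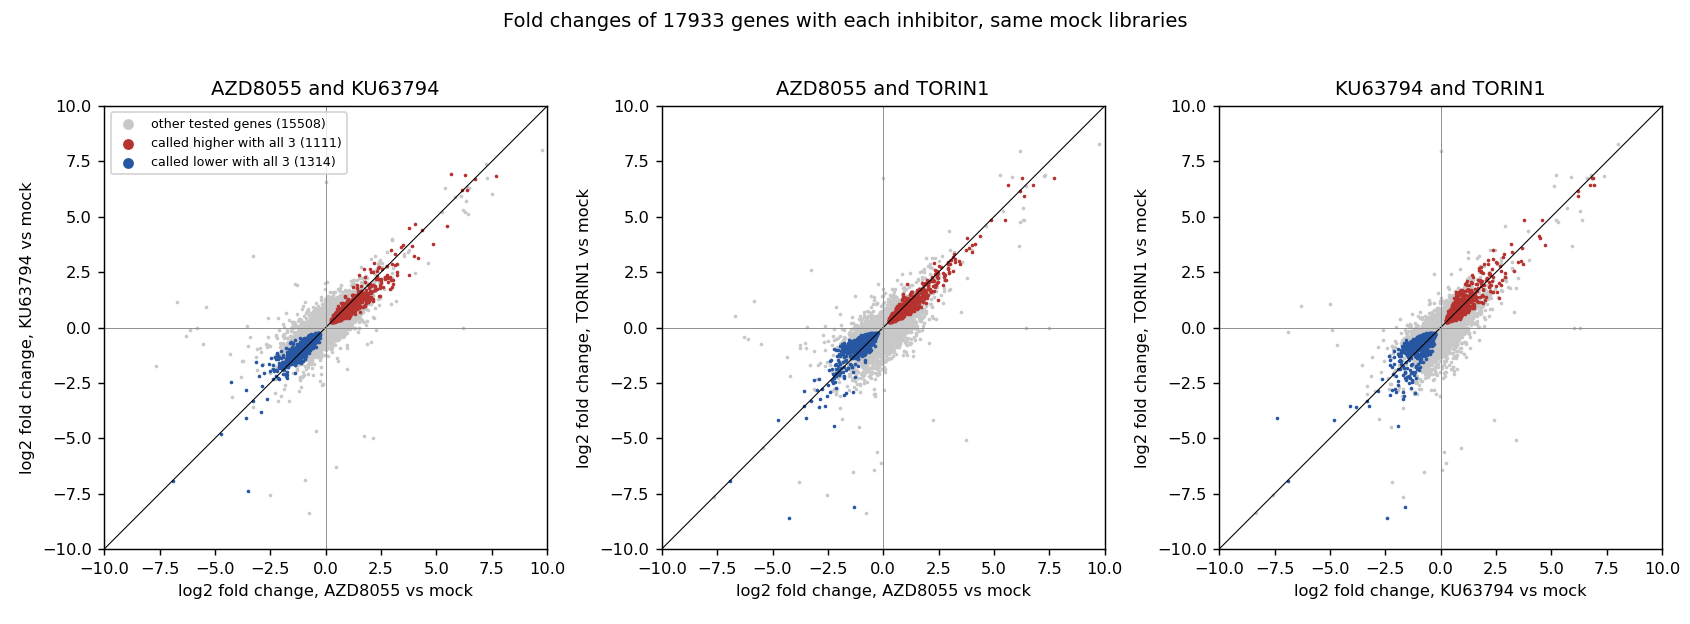
Each point is a gene: its log2 fold change against mock with one inhibitor (x axis) and with another (y axis), in one panel per pair of inhibitors. Genes called with all 3 inhibitors are coloured, 1111 higher and 1314 lower, and lie along the diagonal in each panel.

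Across the 17933 genes the log2 fold changes of AZD8055 and KU63794 correlated with Pearson's r = 0.83, those of AZD8055 and TORIN1 with 0.78 and those of KU63794 and TORIN1 with 0.75; these are correlations across genes, which are not independent replicates. The 3 inhibitors share the mock libraries, and groups simulated with no change, which share simulated controls, gave 0.51, 0.5 and 0.5. Genes were drawn independently there, so deviations common to genes of the real mock libraries are not covered. The covariances of 0.367, 0.345 and 0.303 exceeded the simulated 0.05, 0.049 and 0.049 by 0.317, 0.296 and 0.254. Both AZD8055 and KU63794 raised 1601 genes and lowered 2161, where independent lists of those lengths would share 286 and 413. AZD8055 and TORIN1 shared 1491 higher and 1541 lower genes (254 and 297 for independent lists), and KU63794 and TORIN1 shared 1150 and 1361 (196 and 264). The simulated unchanged groups shared 0 calls. With 3 mock libraries the controls cannot be split into separate sets of at least 2, and part of the excess may come from the shared controls. Of the 6745 genes called with at least 1 inhibitor, 4455 were called in the same direction with at least 2. Another 2287 were called with exactly 1 (1089 with AZD8055, 707 with KU63794 and 491 with TORIN1).

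Among the 24 lists, that of the cytosolic ribosome, the longest, had the most members that fell. RPL14A (AT2G20450) went from 152 ± 2.66 CPM in mock to 47.1 ± 9.96 with AZD8055, 47.2 ± 6.12 with KU63794 and 83.3 ± 1.01 with TORIN1, and RPL9D (AT4G10450) from 53 ± 4.09 to 12.2 ± 3.23, 16.5 ± 1.5 and 26.2 ± 4.57. RPS9B (AT5G15200) had log2 fold changes of -1.52, -1.5 and -1.24 (SE 0.19, 0.19 and 0.18; edgeR adjusted p = 5.91e-05, 8.05e-05 and 0.000719). Genes of cytosolic ribosomal proteins together held 3.77 ± 0.131% of all counts in mock, 1.66 ± 0.329% with AZD8055, 1.68 ± 0.172% with KU63794 and 2.14 ± 0.159% with TORIN1 (mean ± SD, n = 3). Of 191 measured members of this list, 181 fell with AZD8055, 183 with KU63794 and 167 with TORIN1, 10, 8 and 24 did not pass the test, and 0 rose in the edgeR test. Adjusted over the list alone, 185, 188 and 182 fell. Medians were -1.21, -1.28 and -0.77, with camera adjusted p = 3.12e-59, 8.94e-69 and 9.73e-50. With an estimated correlation the adjusted p was 0.299 for each, as it was above 0.05 in all 72 tests of the 24 lists against mock. Members of multigene families such as these can share reads, so single values are less certain than the group.

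Ribosome biogenesis genes fell alongside. NOP5-1 (AT5G27120), a nucleolar protein of the box C/D particles, went from 65.8 ± 0.181 CPM in mock to 20.8 ± 7.58, 24 ± 2.08 and 33.9 ± 6.47, and GAR1 (AT3G03920), of the box H/ACA particles, had log2 fold changes of -1.46, -1.32 and -1.02 (SE 0.2, 0.19 and 0.19). Of 35 members, 32 fell with AZD8055, 31 with KU63794 and 30 with TORIN1, 3, 4 and 5 did not pass the test and 0 rose. Counts adjusted over the list alone were 32, 31 and 33 lower. Medians were -1.3, -1.15 and -0.76, with camera adjusted p = 4.59e-21, 4.94e-21 and 8.06e-18, and adjusted p = 0.299, 0.299 and 0.315 with an estimated correlation. The mean level of the list per library fell by 1.23 log2 units with AZD8055 (95% interval -1.58 to -0.87), by 1.07 with KU63794 (-1.42 to -0.72) and by 0.76 with TORIN1 (-1.11 to -0.41).

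**Figure D2:**
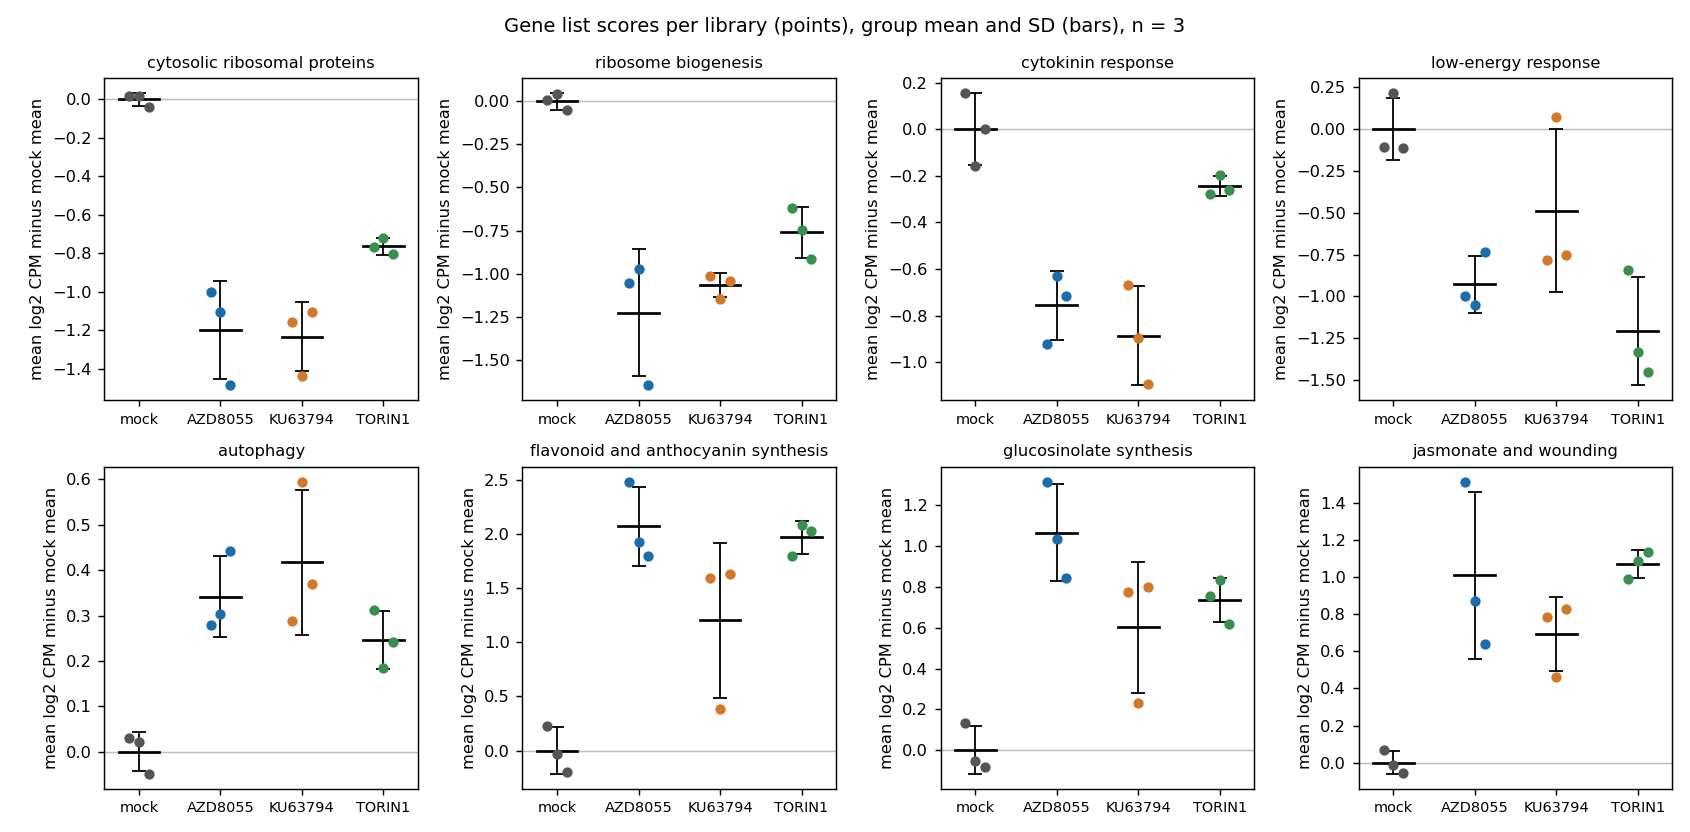
Mean log2 CPM of 8 gene lists in each library relative to the mock mean (y axis, log2 units) by group (x axis), one point per library, with bars for the mean ± SD of 3 libraries. Ribosomal protein and biogenesis scores lie below mock in every inhibitor library, and TORIN1 libraries lie nearer to mock than the others for the cytokinin response list.

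Cytokinin response genes fell with AZD8055 and KU63794. The type-A response regulators are cytokinin-induced repressors of cytokinin signalling. ARR7 (AT1G19050) went from 22.9 ± 3.12 CPM in mock to 10.1 ± 1.3 with AZD8055 and 8.95 ± 1.21 with KU63794, and was 20 ± 3.83 with TORIN1 (log2 fold changes -1.18, -1.36 and -0.2; edgeR adjusted p = 0.000102, 4.08e-05 and 0.429). ARR4 (AT1G10470) changed by -0.83 and -1.04 (SE 0.12), with -0.14 under TORIN1 (edgeR adjusted p = 0.433), and ARR6 (AT5G62920) by -1.14 and -1.2, with -0.15 under TORIN1. ARR5 (AT3G48100), ARR8 (AT2G41310) and ARR9 (AT3G57040) fell with all 3, by 0.96, 0.61 and 0.99 with AZD8055, by 1.05, 0.78 and 0.79 with KU63794 and by 0.59, 0.44 and 0.61 with TORIN1. ARR15 (AT1G74890; -1.83, -2.6 and -0.58) and ARR16 (AT2G40670; -0.29, -0.13 and 0) did not pass the test. Of 10 members, 6, 6 and 3 fell, 4, 4 and 7 did not pass and 0 rose, and adjusted over the list alone 6, 7 and 3 fell. Medians were -0.89, -0.92 and -0.18, with camera adjusted p = 0.00115, 0.000216 and 0.0928 and adjusted p = 0.299, 0.299 and 0.387 with an estimated correlation. The TORIN1 calls did not hold with each library left out. ARR5 lost its call without TORIN1 replicate 2 (edgeR adjusted p = 0.06) or 3 (0.12) or mock replicate 1 (0.0881) or 2 (0.0986). ARR8 lost it without TORIN1 replicate 1 (0.0584) or 3 (0.0572) or mock replicate 1 (0.0859). ARR9 lost it without TORIN1 replicate 1 (0.0534) or 3 (0.0558) or mock replicate 2 (0.0613).

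Cytokinin metabolism genes went both ways. LOG8 (AT5G11950), of the family that activates cytokinin nucleotides, rose from 49.2 ± 4.07 CPM to 91.8 ± 26.9, 99 ± 1.81 and 100 ± 10.1, and LOG5 (AT4G35190) by 0.85, 1.38 and 1.27 log2 units. IPT9 (AT5G20040), a tRNA isopentenyltransferase, had log2 fold changes of -1.02, -1.1 and -0.56 (SE 0.11; edgeR adjusted p = 1.2e-05, 9.13e-06 and 0.00248). Of the cytokinin oxidases, CKX6 (AT3G63440) rose by 0.33 with AZD8055 (SE 0.1; edgeR adjusted p = 0.021), a call lost without AZD8055 replicate 1 (0.0662), mock replicate 2 (0.0739) or mock replicate 3 (0.0793). CKX1, CKX2, CKX4, CKX5 and CKX7 passed with none of the inhibitors. In the list of 17, 4 rose and 2 fell with AZD8055, 3 and 2 with KU63794 and 3 and 1 with TORIN1, with 11, 12 and 13 not past the test and the same counts adjusted over the list alone. Medians were -0.12, 0.09 and -0.1 and camera adjusted p = 0.996, 0.788 and 0.996 (0.998, 0.873 and 0.998 as adjusted p with an estimated correlation). For TORIN1 the median and mean (-0.06) were negative while the direction of the test was up.

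Autophagy genes rose. ATG8H (AT3G06420), a ubiquitin-like protein of the autophagosome membrane, went from 23.8 ± 0.885 CPM to 40.5 ± 5.32, 44.9 ± 8.97 and 39 ± 2.91, and ATG8I (AT3G15580) from 52.5 ± 3.3 to 84.9 ± 14.8, 88.5 ± 2.91 and 80.3 ± 2.48. ATG101 (AT5G66930), a subunit of the kinase complex that starts autophagy, rose by 0.61, 0.85 and 0.61 log2 units (SE 0.15; edgeR adjusted p = 0.00721, 0.000882 and 0.011). Of 36 members, 21, 21 and 12 rose, 15, 15 and 24 did not pass and 0 fell, with 23, 24 and 13 higher when adjusted over the list alone. Medians were 0.41, 0.45 and 0.24, with camera adjusted p = 1.36e-06, 1.51e-09 and 6.25e-05 and adjusted p = 0.346, 0.315 and 0.401 with an estimated correlation. Some genes of the TOR pathway itself also rose by small amounts, fewest with TORIN1. LST8-1 (AT3G18140), a partner of TOR, went from 107 ± 4.26 CPM to 145 ± 1.7, 144 ± 8.52 and 137 ± 1.94, and RAPTOR1B (AT3G08850) rose by 0.49 and 0.4 with AZD8055 and KU63794 (SE 0.1). RAPTOR1B rose by 0.32 with TORIN1 (edgeR adjusted p = 0.0366), a call lost without TORIN1 replicate 1 or 2 or mock replicate 1, 2 or 3. TOR (AT1G50030) rose by 0.35 with AZD8055 and 0.3 with KU63794 (edgeR adjusted p = 0.0135 and 0.0325) and was at 0.21 with TORIN1 (0.16). The AZD8055 call was lost without AZD8055 replicate 3 (0.0619) or mock replicate 1 (0.0578), and the KU63794 call without KU63794 replicate 2 (0.107) or 3 (0.09) or mock replicate 1 (0.114), 2 (0.0689) or 3 (0.0779). Of 11 components, 7, 5 and 2 rose, 4, 6 and 9 did not pass and 0 fell, with 7, 6 and 5 higher adjusted over the list alone, medians of 0.33, 0.3 and 0.21 and camera adjusted p = 0.00927, 0.0126 and 0.00832. With an estimated correlation the adjusted p was 0.315 for each inhibitor.

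Genes of the low-energy response, known as induced by sugar starvation and the kinase SnRK1, fell with AZD8055 and TORIN1, and less clearly with KU63794. BCAT2 (AT1G10070), of branched-chain amino acid breakdown, went from 308 ± 81 CPM in mock to 70.8 ± 16.5 with AZD8055 and 46.5 ± 18.4 with TORIN1. BT2 (AT3G48360) had log2 fold changes of -2.47 with AZD8055 and -1.93 with TORIN1 (SE 0.36 and 0.35). With KU63794, BCAT2 changed by -1.34, a call lost without KU63794 replicate 1 (edgeR adjusted p = 0.0738) or 3 (0.0643) or mock replicate 2 (0.0823), and BT2 by -1.39, a call lost without KU63794 replicate 3 (0.0525) or mock replicate 2 (0.0531). Of 26 members, 13 fell and 1 rose with AZD8055, 7 fell and 1 rose with KU63794, and 19 fell and 0 rose with TORIN1, with 12, 18 and 7 not past the test. Counts lower were 20, 7 and 20 and higher 1, 1 and 0 when adjusted over the list alone. Medians were -0.94, -0.37 and -1.18, with camera adjusted p = 3.65e-06, 0.00539 and 1.69e-12 and adjusted p = 0.494, 0.723 and 0.346 with an estimated correlation. Without KU63794 replicate 1 the KU63794 median was -0.25 and the list no longer passed. The mean level of the list differed from mock by -0.93 with AZD8055 (95% interval -1.47 to -0.39; limma adjusted p = 0.0118), by -0.49 with KU63794 (-1.02 to 0.05; 0.131) and by -1.21 with TORIN1 (-1.75 to -0.67; 0.00285). KU63794 replicate 2 lay at 0.074, against -0.784 and -0.752 in replicates 1 and 3.

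Among flavonoid and anthocyanin genes, DFR (AT5G42800), dihydroflavonol reductase, went from 39.5 ± 10.6 CPM to 333 ± 90.6 with AZD8055, 175 ± 76.2 with KU63794 and 332 ± 36.3 with TORIN1, and its neighbour in the pathway LDOX (AT4G22880) from 10.2 ± 0.223 to 83.9 ± 31.1, 40.1 ± 18.6 and 75.1 ± 8.32. PAP1 (AT1G56650), a MYB activator of these genes, rose by 3.24, 2.5 and 2.94 log2 units (SE 0.52, 0.53 and 0.53; edgeR adjusted p = 0.00138, 0.00733 and 0.00435). Of 15 members, 13, 10 and 12 rose, 0, 1 and 0 fell and 2, 4 and 3 did not pass, with 14, 12 and 12 higher and 0, 1 and 0 lower adjusted over the list alone. Medians were 2.43, 1.72 and 2.52 and camera adjusted p = 1.86e-08, 0.000122 and 1.37e-09, with adjusted p = 0.364, 0.494 and 0.346 with an estimated correlation. KU63794 replicate 2 stood apart, with a mean list level of 0.38 against 1.591 and 1.631 in replicates 1 and 3, and fry did not pass with KU63794 (fry adjusted p = 0.0699). Among glucosinolate genes, CYP83A1 (AT4G13770), an aliphatic glucosinolate enzyme, rose from 8.98 ± 0.915 CPM to 30.7 ± 9.62, 17.9 ± 4.76 and 19.7 ± 1.2. Of 27 members, 19, 11 and 15 rose, 8, 16 and 12 did not pass and 0 fell, with 23, 13 and 16 higher and 0, 1 and 0 lower adjusted over the list alone. The medians were 1.09, 0.61 and 0.82 and camera adjusted p = 1.65e-09, 9.67e-05 and 8.55e-08 (adjusted p = 0.315, 0.494 and 0.346 with an estimated correlation). KU63794 replicate 2 was again lower than replicates 1 and 3, at 0.23 against 0.775 and 0.8, and fry did not pass with KU63794 (fry adjusted p = 0.0611).

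AOC1 (AT3G25760), an allene oxide cyclase of jasmonate synthesis, rose from 5.84 ± 0.126 CPM to 17 ± 3.09, 11 ± 0.665 and 16.6 ± 1.59. In the jasmonate and wounding list of 10 members, 7, 4 and 5 rose, 3, 6 and 5 did not pass and 0 fell, with 7, 4 and 7 higher adjusted over the list alone, medians of 1.12, 0.67 and 1.1, camera adjusted p = 0.000476, 0.00671 and 2.98e-05 and adjusted p = 0.315, 0.387 and 0.299 with an estimated correlation. RD29A (AT5G52310), a dehydration-responsive gene, rose from 10.6 ± 1.48 CPM to 38.4 ± 4.47, 29.6 ± 4.65 and 27.3 ± 7.01, and HAI1 (AT5G59220), a phosphatase gene induced by abscisic acid, by 2.31, 2.33 and 2.11 log2 units. Of 19 members of the abscisic acid and dehydration list, 6, 6 and 4 rose, 0, 0 and 1 fell and 13, 13 and 14 did not pass, with 7, 6 and 4 higher and 0, 0 and 1 lower adjusted over the list alone. Medians were 0.43, 0.52 and 0.21 and camera adjusted p = 0.0102, 0.0272 and 0.122, with adjusted p = 0.494, 0.535 and 0.7 with an estimated correlation. The AZD8055 call of this list was lost without AZD8055 replicate 1 (median 0.2) and the KU63794 call without KU63794 replicate 3 (0.42) or mock replicate 2 (0.34). Its mean level passed with none of the inhibitors (limma adjusted p = 0.2, 0.292 and 0.443). Single libraries stood apart in it: the list level was 0.847, 0.341 and 0.131 in AZD8055 replicates 1 to 3, 0.152, 0.269 and 0.677 with KU63794 and 0.861, -0.062 and 0.04 with TORIN1. The seed storage markers of the same libraries were at 1.716, -0.282 and -3.648, at -3.414, 1.701 and 1.005 and at 1.648, -2.781 and -3.173, so AZD8055 replicate 1 and TORIN1 replicate 1 were the highest of their groups in both lists, while with KU63794 the highest library differed.

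DNA replication genes fell with AZD8055 and KU63794. CDC6A (AT2G29680), a licensing factor, had log2 fold changes of -0.86 and -0.78 (SE 0.18), and RNR2A (AT3G23580), a ribonucleotide reductase subunit, of -0.66 and -0.58 (SE 0.11). Of 19 members, 8, 8 and 1 fell, 11, 11 and 18 did not pass and 0 rose, with 10, 11 and 0 lower adjusted over the list alone, medians of -0.44, -0.43 and -0.28 and camera adjusted p = 9.67e-05, 0.000276 and 0.00821 (adjusted p = 0.494, 0.494 and 0.593 with an estimated correlation). The mean level with TORIN1 did not pass (-0.26, 95% interval -0.55 to 0.03; limma adjusted p = 0.131). Mitosis and cytokinesis genes showed no list call. Of 24, 1 rose and 1, CKS2 (AT2G27970; -0.64 with AZD8055), fell with AZD8055, 0 passed with KU63794 and TORIN1 (22, 24 and 24 not past the test), and 0 were higher and 1, 0 and 0 lower adjusted over the list alone. Medians were -0.08, 0.1 and 0.02 and camera adjusted p = 0.711, 0.55 and 0.879 (0.998, 0.972 and 0.998 as adjusted p with an estimated correlation). With AZD8055 the mean was 0.03 and the direction of the test down, and total-count scaling turned the TORIN1 median to -0.05. In the shoot meristem and leaf growth list, CLV1 (AT1G75820), a receptor kinase of the meristem, rose by 0.73 and 0.66 with AZD8055 and KU63794 (SE 0.14). Of 18 members 1, 1 and 0 rose and 0, 0 and 2 fell, with 17, 17 and 16 not past the test, 1, 1 and 0 higher and 0, 0 and 1 lower adjusted over the list alone, medians of -0.04, 0.11 and -0.24 and camera adjusted p = 0.996, 0.55 and 0.355 (0.998, 0.873 and 0.795 as adjusted p with an estimated correlation). With AZD8055 its mean was -0.02 and the direction of the test up.

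Photosynthesis genes rose with AZD8055 and, in fewer members, with KU63794. LHCB2.3 (AT3G27690), a light-harvesting protein, rose by 1.27, 0.92 and 0.74 log2 units (SE 0.22). Its TORIN1 call (edgeR adjusted p = 0.0315) was lost without TORIN1 replicate 2 or 3 or mock replicate 2 or 3. Of 46 members, 17, 6 and 3 rose, 0, 1 and 6 fell and 29, 39 and 37 did not pass, with 18, 2 and 3 higher and 1, 1 and 6 lower adjusted over the list alone. Medians were 0.3, 0.16 and 0.14 and camera adjusted p = 9.45e-06, 0.0138 and 0.347, with adjusted p = 0.494, 0.754 and 0.924 with an estimated correlation. The mean level with KU63794 did not pass (0.16, 95% interval -0.08 to 0.4; limma adjusted p = 0.257). In the chlorophyll synthesis list of 7, 1, 0 and 2 rose, 6, 7 and 5 did not pass and 0 fell. Adjusted over the list alone, 1, 0 and 2 were higher and 0, 0 and 1 lower, and medians were 0.22, 0.09 and 0.01. GLK1 (AT2G20570), a regulator of chloroplast genes, rose by 0.66 with AZD8055 and 0.46 with TORIN1 (SE 0.14). Its TORIN1 call (edgeR adjusted p = 0.0279) was lost without TORIN1 replicate 1 or 3 or mock replicate 2 or 3. The camera adjusted p was 0.276, 0.552 and 0.672 (0.535, 0.783 and 0.831 as adjusted p with an estimated correlation), and the TORIN1 median was 0 under DESeq2-style size factors and -0.08 under total-count scaling. Of 16 circadian clock genes, 2, 3 and 0 rose, 14, 13 and 16 did not pass and 0 fell. FKF1 (AT1G68050), a blue-light receptor, rose by 1.04 with AZD8055 and 0.91 with KU63794. Its KU63794 call (edgeR adjusted p = 0.0142) was lost without KU63794 replicate 2 or mock replicate 1 or 2. Adjusted over the list alone 2, 1 and 0 were higher, medians were 0, 0.14 and -0.08, the first turning to -0.02 under total-count scaling, and camera adjusted p was 0.55, 0.164 and 0.626 (0.794, 0.494 and 0.82 as adjusted p with an estimated correlation).

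Cell wall expansion genes split into those that rose and those that fell. XTH18 (AT4G30280) rose from 6.81 ± 2.66 CPM to 62.7 ± 29.2, 71.2 ± 37.3 and 41.9 ± 10.4, and XTH15 (AT4G14130) rose by 2.76 and 3.4 log2 units with AZD8055 and KU63794 (SE 0.57). Of 26 members, 12, 11 and 5 rose, 7, 7 and 4 fell and 7, 8 and 17 did not pass, with 12, 12 and 10 higher and 7, 7 and 4 lower adjusted over the list alone. Medians were 0.28, 0.19 and 0.28 and camera adjusted p = 0.195, 0.263 and 0.21 (0.494, 0.535 and 0.497 as adjusted p with an estimated correlation). By mean level the list was higher with each, by 0.49 (95% interval 0.26 to 0.72; limma adjusted p = 0.00364), 0.54 (0.3 to 0.77; 0.00253) and 0.38 (0.15 to 0.62; 0.0129). Of 15 auxin response genes 3, 3 and 1 rose, 12, 12 and 14 did not pass and 0 fell, with the same counts adjusted over the list alone. GH3.5 (AT4G27260), an auxin-conjugating enzyme, rose by 1.31 with KU63794 (SE 0.27) and by 1.02 with AZD8055 (SE 0.28). The AZD8055 call (edgeR adjusted p = 0.0146) was lost without AZD8055 replicate 1 or mock replicate 2 or 3. The medians were 0.14, 0.1 and 0.13 and camera adjusted p = 0.643, 0.211 and 0.688 (0.756, 0.398 and 0.795 as adjusted p with an estimated correlation), while the mean level was higher with KU63794 by 0.23 (0.08 to 0.38; limma adjusted p = 0.0156).

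Nitrate assimilation genes went apart: NRT2.1 rose as given above, while NIA1 (AT1G77760), a nitrate reductase, fell from 358 ± 65 CPM to 127 ± 35.4, 181 ± 57.7 and 148 ± 6.85. Of 13, 3, 2 and 2 rose, 2 fell with each inhibitor and 8, 9 and 9 did not pass, with 3, 2 and 6 higher and 4, 2 and 3 lower adjusted over the list alone. Medians were -0.17, 0.01 and 0.27 and camera adjusted p = 0.88, 0.996 and 0.317 (0.998, 0.998 and 0.812 as adjusted p with an estimated correlation). The mean was 0.23 and the test's direction up with AZD8055, and 0.17 and down with KU63794. Xenobiotic response genes also split: GSTF6 (AT1G02930), a glutathione transferase, rose from 17.5 ± 3.53 CPM to 241 ± 136, 92.3 ± 25.2 and 202 ± 39.5, while UGT74E2 (AT1G05680), a glucosyltransferase, had log2 fold changes of -2.31 with AZD8055 and -2.38 with TORIN1 (SE 0.47). UGT74E2 changed by -1.31 with KU63794 (edgeR adjusted p = 0.035), a call lost without KU63794 replicate 1 or 3 or mock replicate 1 or 2. Of 13, 2, 3 and 3 rose, 3, 2 and 2 fell and 8 did not pass with each, with 2, 3 and 3 higher and 3, 2 and 3 lower adjusted over the list alone. The medians were -0.35, 0.04 and -0.49 and camera adjusted p = 0.926, 0.673 and 0.798 (0.998, 0.922 and 0.972 as adjusted p with an estimated correlation). Of 7 heat and protein-folding genes, HSP70-4 (AT3G12580) rose from 6.85 ± 0.517 CPM to 15.6 ± 4.15 and 12.3 ± 1.46 with AZD8055 and KU63794, and BIP1 (AT5G28540), a chaperone of the endoplasmic reticulum, fell from 175 ± 7.63 to 127 ± 6.32 and 114 ± 14.8. HSP70-4 also rose with TORIN1, to 11.2 ± 0.933 CPM (edgeR adjusted p = 0.0143), a call lost without mock replicate 3. In this list 1 rose with each inhibitor, 1, 2 and 0 fell and 5, 4 and 6 did not pass, with 2, 2 and 1 higher and 3, 2 and 0 lower adjusted over the list alone. Medians were 0.17, -0.17 and 0.25 and camera adjusted p = 0.996, 0.835 and 0.412 (0.998, 0.931 and 0.602 as adjusted p with an estimated correlation), and with AZD8055 the mean was 0 and the test's direction down.

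Markers of other tissues were measured in the same libraries. Of 5 root markers, 0 rose, 1, 2 and 1 fell and 4, 3 and 4 did not pass, with 1, 2 and 3 lower adjusted over the list alone, medians of -0.54, -0.37 and -0.98 and camera adjusted p = 0.211, 0.276 and 0.0525 (0.534, 0.573 and 0.387 as adjusted p with an estimated correlation). Their mean level was lower than mock by limma with AZD8055 (-0.62, 95% interval -1.1 to -0.14; limma adjusted p = 0.0369) and TORIN1 (-0.79, -1.27 to -0.31; 0.0132), and was at -0.55 with KU63794 (-1.03 to -0.07; 0.0611). Mock replicates 1 to 3 were at -0.149, 0.476 and -0.327 in this level, and AZD8055 replicate 3 was at -0.339, near mock replicate 3. PYK10 (AT3G09260), a root beta-glucosidase, changed by -0.69 with KU63794 and -0.54 with AZD8055 (SE 0.16). Its AZD8055 call (edgeR adjusted p = 0.0218) was lost without AZD8055 replicate 2 or mock replicate 2 or 3. All 9 seed storage markers failed the test with each inhibitor, also adjusted over the list alone. Their medians were 0.25, 0.81 and 0.25, their means 0.49, 0.82 and 0.14 and the test's direction down, with camera adjusted p = 0.711, 0.835 and 0.385 (0.989, 0.998 and 0.894 as adjusted p with an estimated correlation). Levels differed widely between libraries of one group. CRA1, a cruciferin, was at 18.6, 19.6 and 23.3 CPM in mock, 53.9, 17.3 and 0 with AZD8055, 0.782, 86.5 and 37.3 with KU63794 and 66.8, 0.793 and 0.687 with TORIN1, for replicates 1 to 3.

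**Figure D3:**
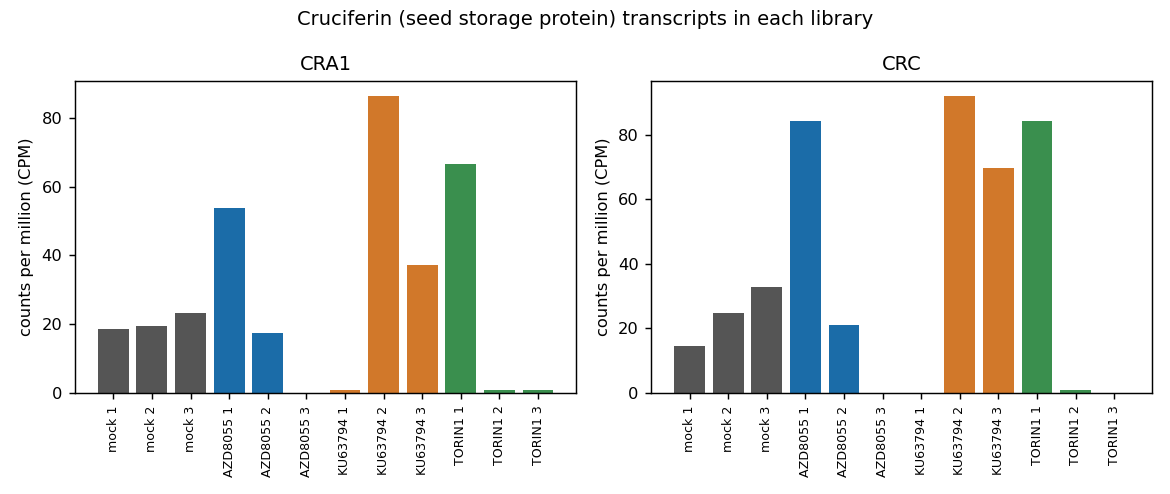
Level of the seed storage genes CRA1 and CRC in CPM (y axis) in each of the 12 libraries (x axis), one bar per library. In mock, CRA1 ranged from 18.6 to 23.3 CPM and CRC from 14.6 to 32.9. In each inhibitor group the highest and lowest library differ by more than in mock.

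With AZD8055, GSTF5 (AT1G02940), a glutathione transferase, rose by 4.64 log2 units (SE 0.98; edgeR adjusted p = 0.00317) from 0.0913 CPM, under the limit of a count of 0, to 3.22 ± 1.18. CSLA01 (AT4G16590), of the cellulose synthase-like family, had no count in mock and 239, 65 and 16 counts in AZD8055 replicates 1 to 3 (edgeR adjusted p = 0.0391), so its size of change rests on replicate 1 and is not given. Its call was lost without AZD8055 replicate 1 (0.0676) or 2 (0.0589) or mock replicate 1 (0.09), 2 (0.081) or 3 (0.0716). CSLA01 also had 69, 0 and 38 counts in KU63794 replicates 1 to 3 and 35, 31 and 46 in those of TORIN1. With AZD8055 2577 genes were higher and 2884 lower by edgeR, 538 and 829 of them at least 2-fold.

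With KU63794, GPT2, AT1G20515 and AT2G20142 were among the 5 genes with the largest rises, as given above, and AT2G04050 and AT1G70880 among those with the largest falls. BGLU21 (AT1G66270), a beta-glucosidase, changed by -2.95 (SE 0.86; edgeR adjusted p = 0.0363), from 48.3 ± 28 to 6.29 ± 1.84 CPM. That call was lost without KU63794 replicate 1 (0.0941), 2 (0.0873) or 3 (0.112), without mock replicate 1 (0.117) or 2 (0.0741), and under total-count scaling (0.0515). KU63794 raised 1988 genes and lowered 2567, 374 and 683 of them at least 2-fold. The share higher was 43.6% of 4555 calls and 54.3% of 4375 under total-count scaling.

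With TORIN1, NDB3 (AT4G21490), a mitochondrial NAD(P)H dehydrogenase, had no count in any library and was at least 10.5-fold lower than the mock level of 3.01 ± 0.0666 CPM (edgeR adjusted p = 0.000169). GSTF5 rose by 4.58 log2 units (SE 0.98; edgeR adjusted p = 0.00588). TORIN1 raised 1770 genes and lowered 1844, 319 and 361 of them at least 2-fold. Without mock replicate 2 these counts were 1102 and 1112, without TORIN1 replicate 3 they were 1076 and 1166, and without TORIN1 replicate 2 the count lower was 1191. The share higher was 49% of 3614 calls and 36.6% of 3358 under total-count scaling.

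Few genes were called between AZD8055 and KU63794 at these doses, which does not show that their effects were equal. In the simulated comparison edgeR recovered 17.9% of genes changed 1.5-fold, so small differences can be missed. AT5G08400, a gene of unknown function, was higher with AZD8055, at 25.3 ± 2.82 against 11.6 ± 0.827 CPM and 21.1 ± 1.93 in mock (log2 1.12, SE 0.12; edgeR adjusted p = 0.00357), and lost its call without KU63794 replicate 3 (log2 1.08, 0.0642). The mean ribosomal protein level differed by 0.03 log2 units (95% interval -0.25 to 0.32), cytokinin response by 0.13 (-0.15 to 0.4) and autophagy by -0.08 (-0.27 to 0.12). Flavonoid and glucosinolate genes did not pass by limma, at 0.87 (0.16 to 1.57) and 0.46 (0.09 to 0.84), with limma adjusted p = 0.132 for both. Of either list 0 members were called, and 3 and 4 were higher adjusted over the list alone. Their camera adjusted p was 3.58e-13 and 1.14e-11, and the adjusted p 0.482 for both with an estimated correlation. KU63794 replicate 2 was below replicates 1 and 3 in both lists, at 0.38 against 1.591 and 1.631 and at 0.23 against 0.775 and 0.8. By edgeR 1 gene was higher and 0 were lower, while 828 and 670 had an unadjusted p below the same threshold. DESeq2 called 12 higher and 3 lower, and limma voom 1 and 0. The counts were 2 and 1 without KU63794 replicate 2 and 0 higher without KU63794 replicate 3.

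Between AZD8055 and TORIN1, HDT4 (AT2G27840), a plant-specific histone deacetylase, differed. It was at 50.2 ± 1.94 CPM in mock, 10.7 ± 2.55 with AZD8055, 13.1 ± 2.67 with KU63794 and 25.8 ± 1.77 with TORIN1 (AZD8055 against TORIN1 -1.27, SE 0.16; edgeR adjusted p = 0.00444). NDB3 was at least 4.15-fold higher with AZD8055 than with TORIN1 (edgeR adjusted p = 0.0155), a call lost without TORIN1 replicate 2 (0.0618) or 3 (0.083). In the ribosomal protein list 52 of 191 members were lower with AZD8055, 0 higher and 139 not past the test, and 116 were lower adjusted over the list alone. RPL14A differed by -0.82 (SE 0.13; edgeR adjusted p = 0.0126), a call lost without TORIN1 replicate 2 (0.0605) or 3 (0.0753). The mean level of the list differed by -0.44 (95% interval -0.72 to -0.15; limma adjusted p = 0.0948), with camera adjusted p = 1.78e-39 and adjusted p = 0.482 with an estimated correlation. Of 10 cytokinin response genes 3 were lower, also adjusted over the list alone, and the list differed by -0.51 (-0.79 to -0.24; limma adjusted p = 0.0745), with camera adjusted p = 0.000442 and adjusted p = 0.329 with an estimated correlation. AZD8055 was higher in 89 genes and lower in 234, and 45 and 15 of these were at least 2-fold. The counts higher and lower under total-count scaling were 40 and 21. Without TORIN1 replicate 2 they were 13 and 6, without TORIN1 replicate 3 they were 7 and 7, and without AZD8055 replicate 3 they were 32 and 29. The count higher was 42 without AZD8055 replicate 1, 137 without AZD8055 replicate 2 and 58 without TORIN1 replicate 1.

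Between TORIN1 and KU63794, ARR4 was higher with TORIN1 by 0.89 log2 units (SE 0.12; edgeR adjusted p = 0.00743) and ARR7 by 1.16 (SE 0.17; edgeR adjusted p = 0.0103). ARR4 lost its call without TORIN1 replicate 2 (0.0552) or 3 (0.0659), and ARR7 without TORIN1 replicate 2 (0.0603) or 3 (0.07). Of 10 cytokinin response genes 3 were higher, 0 lower and 7 not past the test, with 5 higher adjusted over the list alone, and the mean level differed by 0.64 (95% interval 0.37 to 0.92; limma adjusted p = 0.0312), with camera adjusted p = 0.000263 and adjusted p = 0.329 with an estimated correlation. In the ribosomal protein list 68 members were higher with TORIN1, 0 lower and 123 not past the test, 134 were higher and 1 lower adjusted over the list alone, and the mean level differed by 0.47 (0.19 to 0.75; limma adjusted p = 0.0868; camera adjusted p = 1.15e-38; adjusted p = 0.482 with an estimated correlation). Low-energy genes did not pass by limma, at -0.72 (-1.26 to -0.18, limma adjusted p = 0.132), with 1 member lower and 14 lower adjusted over the list alone. The camera adjusted p was 7.78e-13, and 0.614 with an estimated correlation. KU63794 replicate 2 stood apart in this list, at 0.074 against -0.784 and -0.752 in replicates 1 and 3. GA3OX1 (AT1G15550), a gibberellin synthesis gene, was higher with TORIN1 by 2.05 (SE 0.42; edgeR adjusted p = 0.0278), a call lost without TORIN1 replicate 2 (0.0878) or 3 (0.158), KU63794 replicate 1 (0.0537) or 2 (0.13), and under total-count scaling (0.0537). TORIN1 was higher in 397 genes and lower in 108, 19 and 42 of these at least 2-fold, and the counts under total-count scaling were 26 and 67. The counts were 2 and 3 without TORIN1 replicate 2, 1 and 1 without TORIN1 replicate 3, 17 and 9 without KU63794 replicate 2, and 668 and 267 without TORIN1 replicate 1, and 126 were higher without KU63794 replicate 1. TORIN1 replicates 2 and 3, on which both comparisons of TORIN1 with another inhibitor rest, also had the lowest CRA1 levels of that group, and with the seed marker level as a covariate, a choice made after seeing the data, 215 were higher and 65 lower.

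**Figure D4:**
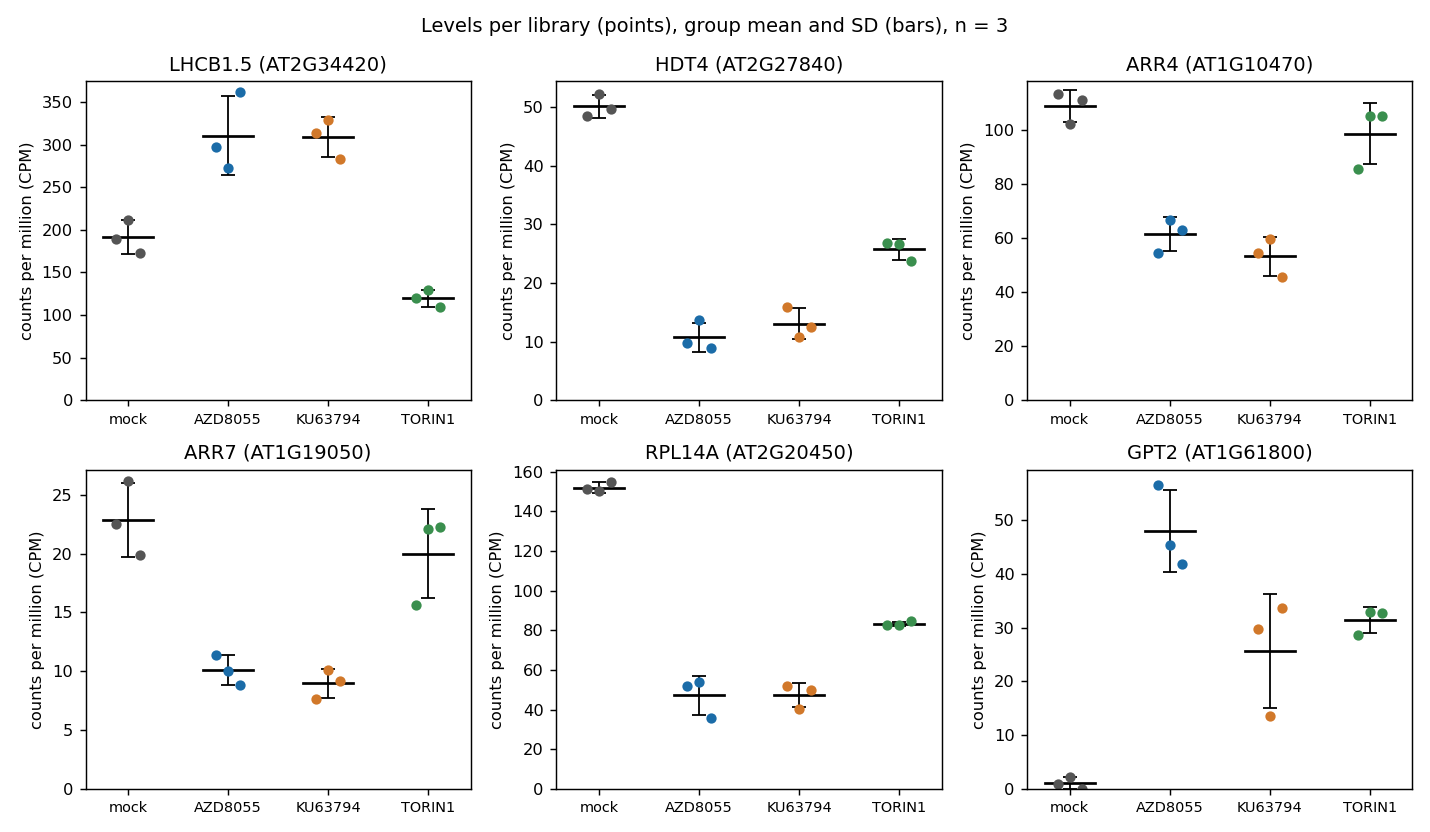
Levels of LHCB1.5, HDT4, ARR4, ARR7, RPL14A and GPT2 in CPM (y axis) by group (x axis), one point per library, with bars for the mean ± SD of 3 libraries. HDT4 with TORIN1 lies between mock and the other inhibitors, and LHCB1.5 lies below mock with TORIN1 and above it with AZD8055 and KU63794.

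There were 5 genes called in opposite directions by 2 inhibitors, named here after their values were seen. LHCB1.5 (AT2G34420), a light-harvesting protein of photosystem II, was at 192 ± 19.7 CPM in mock, 311 ± 46.2 with AZD8055, 309 ± 23.5 with KU63794 and 119 ± 10.1 with TORIN1 (log2 0.7, 0.69 and -0.69, SE 0.12; edgeR adjusted p = 0.000477, 0.000642 and 0.0013). It kept its calls with each library left out, and AZD8055 exceeded TORIN1 by 1.38 (edgeR adjusted p = 0.000188). LHCB1.4 (AT2G34430), its near-identical relative, had 0.72, 0.54 and -0.76, PSAG (AT1G55670), a photosystem I subunit, 0.54, 0.14 and -0.58, HCD1 (AT4G14440) 0.56, 0.15 and -0.7, and AT1G63360 0.72, 0.02 and -0.78. Because reads of LHCB1 copies can be exchanged, their 5 genes were also summed, to 1370 ± 136 CPM in mock, 1680 ± 237 with AZD8055, 1420 ± 72.7 with KU63794 and 773 ± 108 with TORIN1. The other 4 genes lost calls against mock when single libraries were left out. LHCB1.4 lost its KU63794 call without KU63794 replicate 1 (edgeR adjusted p = 0.0799) or 2 (0.183) or mock replicate 1 (0.0966) or 3 (0.168), and its TORIN1 call without TORIN1 replicate 3 (0.0628) or mock replicate 2 (0.0619). PSAG lost its AZD8055 call without AZD8055 replicate 1 (0.0684) or 3 (0.12) or mock replicate 1 (0.0886) or 3 (0.101), and its TORIN1 call without TORIN1 replicate 1 (0.0882) or 3 (0.135) or mock replicate 1 (0.0702) or 2 (0.129). HCD1 lost its AZD8055 call without AZD8055 replicate 1 (0.0733) or 3 (0.0525) or mock replicate 2 (0.0993) or 3 (0.0726), and its TORIN1 call without TORIN1 replicate 1 (0.0743) or mock replicate 1 (0.0904). AT1G63360 lost its AZD8055 call without AZD8055 replicate 1 (0.0567) or 3 (0.057) or mock replicate 1 (0.0827) or 3 (0.061), and its TORIN1 call without TORIN1 replicate 1 (0.0609) or 2 (0.107) or mock replicate 2 (0.139).

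The authors' deposited tables list 5308, 4558 and 3696 genes for AZD8055, KU63794 and TORIN1 against mock. Of these, 96.1%, 94.3% and 93.1% were also called here, and 0 had the opposite sign once the deposited fold changes, which are mock over inhibitor, were turned. The authors' deposited final list holds 4398 genes, 2066 higher and 2332 lower with the inhibitors, of which 2507 are in all 3 of their tables and 1891 in exactly 2. It includes 2399 of the 2425 genes called here with all 3.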

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

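The alternatives here were chosen before the data were examined, except the seed covariate and the removal of all-or-none genes, which were added after the first results were seen. Unless a reason is given, the cause was not tested.

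Against mock, a further demand of a 2-fold change left 538 higher and 829 lower genes with AZD8055, 374 and 683 with KU63794, 319 and 361 with TORIN1 and 164 and 124 with all 3; a stricter demand can only lower a count. The mean of the 3 inhibitors against mock gave 2725 higher and 3158 lower genes, a test that does not ask for a call with each inhibitor. With one library of the groups compared left out, counts were 1844 to 2461 higher and 2200 to 2733 lower with AZD8055, 1376 to 1743 and 1914 to 2156 with KU63794, and 1076 to 1583 and 1112 to 1569 with TORIN1. Leaving out a library of another group, which leaves the compared libraries as they are, also moved calls, to 5137 with KU63794 and 4192 with TORIN1 without AZD8055 replicate 1 and to 5669 with AZD8055 without KU63794 replicate 2, against 4555, 3614 and 5461. The order of the inhibitors by calls was not stable: a fit of only the 2 groups gave 4914 with AZD8055 and 5080 with KU63794. With any one of the 12 libraries left out, the shared counts ranged from 709 to 1279 higher and from 801 to 1489 lower.

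Comparisons of inhibitors with each other moved most. For AZD8055 against KU63794, DESeq2 called 12 higher and 3 lower, a fit of only the 2 groups called 0 higher, and leaving out one library of these groups gave 0 to 2 higher and 0 to 1 lower. For AZD8055 against TORIN1, total-count scaling gave 40 and 21, DESeq2 153 and 440, limma voom 44 and 153, a fit of only the 2 groups 5 and 6, and a 2-fold demand 45 and 15. Leaving out one library of these groups gave 7 to 137 higher and 6 to 303 lower. For TORIN1 against KU63794, DESeq2-style size factors gave 224 higher, total-count scaling 26 and 67, DESeq2 822 and 308, a fit of only the 2 groups 130 and 28, a 2-fold demand 19 and 42, and leaving out one library of these groups 1 to 668 higher and 1 to 267 lower. With the seed marker level as a covariate, 215 were higher and 65 lower.

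A replicate block pairs libraries by their number, although the labels do not say that numbers pair samples. It called 2 genes higher for AZD8055 against KU63794 and 37 higher and 119 lower for AZD8055 against TORIN1. Of 18 pairs of libraries with the same number, 2 had deviations correlated above 0.1, and 5 of 12 libraries matched best with their own number.

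Over genes of at least 10 CPM, correlations were 0.93 for AZD8055 with KU63794, 0.9 for AZD8055 with TORIN1 and 0.83 for KU63794 with TORIN1. Simulated unchanged groups that shared simulated mock libraries gave 0.5, 0.51 and 0.5. Over all tested genes, with one mock library left out, the correlations ranged from 0.83 to 0.87, from 0.78 to 0.83 and from 0.75 to 0.81.

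Of the 72 list tests against mock, 33 passed with the preset correlation, 0 with an estimated correlation, 31 with fry and 32 to 35 with one library left out. The 6 lost with fry were low-energy response, photosynthesis, abscisic acid, glucosinolate and flavonoid genes with KU63794 and DNA replication with TORIN1, and 4 were gained. The seed storage list with KU63794 had medians of 0.05 to 1.39 with one library left out, and without KU63794 replicate 1 the direction of its test reversed, with camera adjusted p = 0.0447. Of the calls of named genes, 289 were kept and 7 lost with DESeq2-style size factors, 273 and 23 with total-count scaling, 274 and 5 with DESeq2, which gave no adjusted p for another 18, and 276 and 20 with the replicate block. With one library left out, 11 to 43 were lost. Under these choices 0 were reversed; the other alternatives were not run on the named calls.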

Other observations

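Lower ribosomal protein and ribosome biogenesis mRNAs and higher autophagy genes are the directions known from loss of TOR activity in plants and other eukaryotes. Of 36 autophagy genes 21, 21 and 12 passed with AZD8055, KU63794 and TORIN1, and these list calls, like all 33, were lost with an estimated correlation. Of 10 cytokinin response genes 6 fell with AZD8055 and 6 with KU63794, and the mean level of that list was higher with TORIN1 than with KU63794 by 0.64 log2 units (limma adjusted p = 0.0312), while camera gave an adjusted p of 0.329 with an estimated correlation. Whether the doses of 2, 20 and 10 µM were matched for TOR activity is not known here, since TOR activity was not analysed.

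These tests were made on groupings of the libraries. For each comparison of 3 with 3 libraries the 10 splits are too few to exclude chance: 2577 and 2884 genes with AZD8055 against a highest other of 1, 1988 and 2567 with KU63794 against 1, 1770 and 1844 with TORIN1 against 0, 1 and 0 for AZD8055 against KU63794 against 1, 89 and 234 for AZD8055 against TORIN1 against 12, and 397 and 108 for TORIN1 against KU63794 against 1. Places of the real split were 1 for each, except 3 and 10 for AZD8055 against KU63794. For the genes called with all 3 inhibitors, 46 groupings of the 12 libraries were compared, the real one included. The others gave at most 1, against 1111 higher and 1314 lower, place 1 for both. This argues against a random assignment of these libraries to groups. It cannot exclude a difference between cultures, since the labels do not say whether the libraries of a group came from separate cultures.

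Of the tests on low-energy genes, the one on scaling was chosen after the result was seen and the one on sugar genes before. The median with TORIN1 was -1.18 under the scaling that gives the smallest fall. The scalings compared put the median of all genes with TORIN1 at -0.013, -0.019 and -0.088, so they could hardly have removed the fall. The test shows only that the fall does not depend on the choice among them. In a sugar-replete-like state, genes known as sugar-induced would rise, and a separate list of 10 such genes had a second highest median of 0.8 among the inhibitors, with GBSS1 (AT1G32900), a starch synthase, at 2.43, 1.8 and 2.02. Adjusted over its own tests against mock alone, the list passed with an estimated correlation too (camera adjusted p = 0.0332, 0.0416 and 0.0322). The lists that failed with an estimated correlation were adjusted over 72 tests, so their adjusted values cannot be compared with these. As an example, the ribosomal protein list had unadjusted camera p = 0.0195, 0.0136 and 0.0287 with an estimated correlation. A sugar-replete-like transcript state is consistent with this value of 0.8, while sugar levels were not analysed here.

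Of the tests on seed storage transcripts, which differed between libraries of one group, both were chosen after the result was seen. A first form, which asked that the highest and the lowest library match the storage list in all 3 inhibitor groups, was met by 0 of 9 separate seed genes and 1 of 19 abscisic acid genes, with 0.46% expected by chance. It was then changed to the highest library alone, because the storage list lies low in both TORIN1 replicates 2 and 3 (mean log2 CPM -1.46 and -1.85), where their order was taken for counting noise; this was not tested, and does not hold for the seed gene PER1, with 0 and 21 counts there. In that form 8 of 9 seed genes matched and 4 of 19 abscisic acid genes, with 3.7% expected by chance. The seed genes PAP85 and ATS1 had 0 counts in both of these TORIN1 libraries, so their lowest library is a tie that the first form cannot judge. The first form thus rests in part on the order of these libraries, and the changed form was chosen after the first had failed. Seed tissue in some libraries therefore stays open. So does an abscisic acid response of the seedlings, since 4 of 19 is above chance.

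Of the tests on the 139 all-or-none genes, which had 0 counts in one library and at least 30 in another of its group, those on overlap and near-identical genes were chosen before and the one on seed tissue after the result was seen. Overlap with another gene was about as frequent as in other genes (ratio 1.03, interval 0.81 to 1.27, Fisher's exact p = 0.856). This argues against overlapping gene models as the source for the set as a whole. It cannot decide for a smaller part of it. Overlap was scored on whole gene spans of either strand, and 47 of the 139 genes had their highest library where the storage list had it. Near-identical genes had a ratio of 1.24 (0.64 to 2.36; Fisher's exact p = 0.539), which leaves reads shared between near-identical genes open. Outside the seed lists 25.4% had their highest library where the storage list had it, against 4.6% of other genes, which leaves seed tissue in some libraries open.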
